A study of Mus musculus with 4 samples.

How the data were processed

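Small RNA from RAW264.7 cells and from their extracellular vesicles was measured in 4 libraries, 1 per combination of compartment (cells or vesicles) and hairpin (shNS or shDis3l2). Per the labels' protocols, the libraries were made with the QIAseq miRNA kit and read for 50 nt on a NextSeq instrument, and the vesicles came from differential centrifugation and a sucrose gradient with micrococcal nuclease treatment. Per the submitters' processing notes, adapters were removed with cutadapt and reads were assigned with Salmon and Novoalign, with genome builds GRCm38 and mm10 named and no versions given. The deposited values are estimated counts per transcript, of which 6.56% of those above 0 are whole numbers within 0.001. Whether reads were collapsed to molecules by their tags is not given in the sources used here.

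The table holds 141239 features. Of these, 139791 were named from GENCODE M21 (GRCm38), 239 are tRNAs and 8 are SINE or 4.5S sequences. The other 1201 are Ensembl transcripts without a name in that release, which held at most 0.134% of the counts of a library and entered totals only. The table does not mark miRNAs, so the 2022 transcripts typed as miRNA by the annotation were taken as miRNA hairpins, 1148 of them with a symbol starting with Mir and 906 with a count. A value is that of a hairpin, with both arms in it. Another 185 hairpins of the annotation are not among the features. Values were rounded to whole numbers before intervals and fits were computed, and transcripts of 1 gene were summed for genes other than miRNAs.

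Depth ranged from 17612856 to 19741041 counts per library, and from 1854287 to 13480443 counts on miRNA hairpins. Hairpins with at least 100 counts numbered 176 and 174 in the cell libraries labelled shNS and shDis3l2 and 170 and 164 in the vesicle libraries. For a feature at 0 in 1 library, a bound was computed from a floor of 3 counts in that library.

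The following choices were made before the data were examined, except where a later one is named. For each of 4 comparisons (the hairpin labels in cells and in vesicles, and vesicles against cells under each label) the log2 ratio of CPM, scaled to the miRNA total, was computed with a pseudocount of 0.5 for hairpins with at least 100 counts over the 2 libraries. Exact conditional (Clopper-Pearson) 95% intervals were added. A hairpin counts as apart when its ratio is at least 2-fold and the interval excludes 1. No p-value was computed for single comparisons. The difference between the label ratios of vesicles and cells, and the correlation of ratios across hairpins, used all 4 libraries. As later choices, classes of RNA and the lists of other genes were scaled to the total of all features, and tRNAs were summed by anticodon.

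Named hairpins are, per comparison, the 10 with the largest ratio in each direction among those with at least 50 CPM in 1 library and an interval that excludes 0. The rule adds the 10 most abundant of each library, measured members of the fixed lists, the 5 largest differences in each direction between the label ratios, and Dis3l2. tRNA families, snoRNA and snRNA classes, and long transcripts lie outside this rule and were picked after the values were seen.

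Of the 18 lists, 15 hold miRNAs: the let-7, miR-15-16, miR-29 and miR-30 families; the miR-17-92 and miR-23-27-24 clusters; inflammation-responsive, myeloid and haematopoietic, and Drosha-independent capped miRNAs; and markers of erythroid cells and serum, muscle, epithelium, endothelium and mesenchyme, neurons and pluripotent cells. The other 3 hold interferon-stimulated genes, structured Pol III and RNP RNAs, and RNA decay and tailing genes. A list with at least 3 measured members was described by its median and the percentile of that median among 10000 random lists of the same size, matched on mean expression in 4 bins. Random members were drawn singly, so genomic clusters were not kept together.

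Alternatives set in advance were edgeR TMM factors, DESeq2 size factors, the total of all features or the miRNA total without its 5 most abundant members as the scale, count minimums of 10 and 1000, and a pseudocount of 5. They also included thinning to the smallest miRNA total, summing hairpin copies of 1 miRNA, and additive edgeR quasi-likelihood and DESeq2 fits of compartment and label over the 4 libraries (1 residual degree of freedom). Alternatives added after the data were examined were host units, in which a hairpin is summed with a transcript of the same strand whose exon holds it where that transcript has at least 10% of the joint counts (71 units), the restriction to symbols starting with Mir, and the miRNA total as the scale of the 3 other lists.

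The listing of hairpins, the random lists (for the labels in cells) and the additive fits were tested on simulated counts drawn at the real means and depths with 200 features changed. The differences between label ratios, the correlations, the overlaps and the cluster shuffling were not. In the comparison of labels in cells, 100% of the 21 tested features changed 3-fold and 100% of the 21 changed 4-fold were listed in the right direction, and 0% of the 149 unchanged ones. For vesicles against cells with the label shNS, 94.7% of 19 features changed 3-fold were listed, and with the label shDis3l2 0.662% of 151 unchanged ones were. The counts simulated for this listing held counting noise alone, so false listings from variation between libraries were not tested. Such variation was added only in the simulation of the additive fits. Random lists without a shift had a mean percentile of 51.6, and 100% of 100 shifted lists lay above percentile 95. The additive edgeR fit recovered 98.7% of 77 features changed 4-fold between compartments and called 9.26% of unchanged ones, and DESeq2 88.3% and 7.41%.

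Stretches of at least 18 nt shared between annotated transcript sequences were searched for Dis3l2, Gm24379, Gm42427, Gm43305 and named hairpins without a Mir symbol. Named hairpins with a symbol starting with Mir were not searched, so sequence they may share with other RNAs is not described. tRNA and SINE sequences were not searched, and no read-level file was analysed here, so read lengths, arms, tails and positions on a transcript are not described. The versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.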

Results

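Small RNAs were sequenced from cells of the mouse macrophage-like line RAW264.7 and from the extracellular vesicles that these cells released into the medium. The cells carried a doxycycline-induced short hairpin RNA, either a non-silencing control (shNS) or a hairpin against Dis3l2 (shDis3l2), which encodes a cytoplasmic exonuclease that degrades RNAs with oligouridine tails. Doxycycline at 1 µg per mL was given for 3 days before the medium was replaced by one with vesicle-depleted serum, and vesicles were collected over the next 24 h, floated in a sucrose gradient and treated with nuclease. Compartment and hairpin together give 4 groups of 1 library each, so none of the differences below has a replicate check.

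The deposited table gave a total of 19741041 estimated counts for the cell library labelled shNS and 18416554 for the cell library labelled shDis3l2. The vesicle libraries held 18190135 counts with the label shNS and 17612856 with the label shDis3l2. Hairpins annotated as miRNA genes took 13480443 and 11273350 of the counts in cells, and 3477466 and 1854287 of those in vesicles, in the same order. A count of 0 therefore allows up to 0.223 and 0.266 CPM of miRNA counts in the cell libraries and up to 0.863 and 1.62 in the vesicle libraries, with a floor of 3 counts per library. Intervals are exact 95% intervals and, like these floors, cover counting error only, because each group has 1 library. It is also not known whether the reads were collapsed to molecules, so even counting error may be understated.

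Dis3l2 went against the label of the cells that should have had less of it. It had 42 counts in the cell library labelled shNS and 13232 in the cell library labelled shDis3l2, or 2.13 and 719 CPM over all features. That is 334-fold higher (95% interval 250 to 469) in the library labelled shDis3l2, the rank 6 ratio of 3201 genes tested. In vesicles the gene had 1713 counts with the label shNS and 1894 with the label shDis3l2, a 1.14-fold difference (1.07 to 1.22) and rank 5131 of 8302. Of the 6 Dis3l2 transcripts in the table, 1 held nearly all counts of the cell library labelled shDis3l2 (13208) and most of those in both vesicle libraries. It is a transcript of the nonsense-mediated decay type on chromosome 1 from 86703828 to 87049195 (GRCm38). In the cell library labelled shNS it held 19.6 of the 42 counts, and a retained-intron transcript held 13.8. The gene itself spans 86703808 to 87050095 on the plus strand. A lower total count of the gene with the label shDis3l2 was thus not seen in cells or vesicles. From few counts, 1 protein-coding transcript did go with the label. It had 7.74 counts in cells and 13.0 in vesicles with the label shNS, and 0 in both libraries labelled shDis3l2. Every library is named below by its label.

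The makeup of the libraries differed between cells and vesicles. miRNA hairpins took 68.3% of counts in the cell library labelled shNS and 61.2% in that labelled shDis3l2, against 19.1% and 10.5% in vesicles. tRNAs, which carry amino acids to the ribosome, took 4.04% and 5.18% in cells and 38.5% and 35.4% in vesicles. The share of snoRNAs and scaRNAs, the guides of rRNA and snRNA modification, was 8.70% and 11.1% in cells and 0.436% and 0.272% in vesicles. Y RNAs, 7SL, vault RNAs and other RNAs annotated as miscellaneous took 0.699% and 1.68% in cells and 4.67% and 3.47% in vesicles. Gm24379, which shares 24 nt with Rny1, held 78782 of 137912 and 205277 of 308733 of these counts in cells. In vesicles it held 374351 of 850118 and 137541 of 610565, so the shares do not describe Y, 7SL and vault RNAs alone. Protein-coding transcripts took 3.35% and 4.31% in cells and 12.9% and 16.9% in vesicles.

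**Figure D1:**
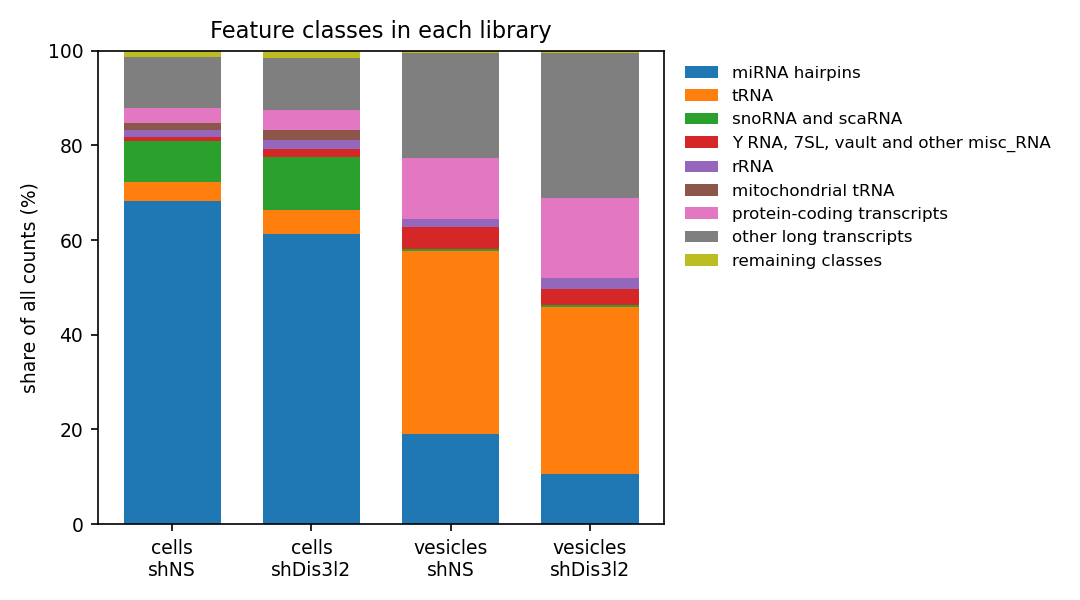
Stacked bars give the share of all counts, in percent, of each feature class in the 4 libraries named by their labels, with 1 library per bar. miRNA hairpins take 68.3% and 61.2% in cells and 19.1% and 10.5% in vesicles, and tRNAs 38.5% and 35.4% in vesicles.

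The most abundant hairpin in each of the 4 libraries was Mir16-1, of the cell-cycle-restraining miR-15-16 family, with 12.5% and 15.2% of miRNA counts in cells and 13.5% and 13.7% in vesicles. Mir142 and Mir191, which are abundant in blood cells, the let-7 hairpins Mirlet7i, Mirlet7a-1, Mirlet7c-2 and Mirlet7f-1, and Mir125b-2 were also among the 10 most abundant of every library, and Mirlet7f-2 of all but the vesicle library labelled shDis3l2. Mir21a, which inflammatory signals induce, took 5.91% in the cell library labelled shNS and 6.50% in the vesicle library labelled shNS. It took 3.10% in the vesicle library labelled shDis3l2 and was not among the 10 of the cell library labelled shDis3l2. Mir146, the hairpin of miR-146a that restrains NF-kB signalling, was among the 10 in both libraries labelled shDis3l2, with 3.55% in cells and 3.36% in vesicles. The 10 together held 59.2% and 63.7% of miRNA counts in cells and 59.9% and 57.6% in vesicles.

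The first comparison asked which miRNAs differ between the cell libraries labelled shDis3l2 and shNS. In the cell library labelled shDis3l2, Mir9-2, a hairpin of the Toll-like-receptor-induced miR-9, was lower than in the library labelled shNS by a log2 ratio of -3.46 (95% interval -3.61 to -3.31), from 4902 and 373 counts. Mir132, a CREB-induced miRNA, was 6.16-fold lower (-2.62, -2.89 to -2.37), and its neighbour Mir212, from the same primary transcript, had a log2 ratio of -2.87. Mir34a, a p53 target, was 5.17-fold lower, and Mir21a 2.26-fold lower. Mir152 was 7.38-fold higher (2.88, 2.77 to 3.01), the endothelial Mir126a 5.25-fold higher (2.39, 2.34 to 2.45) and Mir187, which interleukin-10 induces in monocytes, 4.13-fold higher.

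Of 206 hairpins with at least 100 counts over these libraries, 15 were at least 2-fold higher and 19 at least 2-fold lower in the library labelled shDis3l2. With TMM factors the split was 16 higher and 15 lower, with all features as the scale 10 and 22, and without the 5 most abundant miRNAs in the scale 18 and 13. The median of all hairpins was 0.03 on the log2 scale, 0.11 with TMM factors, 0.07 with DESeq2 size factors and -0.12 with all features as the scale. The 3 hairpins of the miR-99b cluster on chromosome 17 were lower together: Mir125a 3.33-fold, Mir99b 3.09-fold and Mirlet7e 3.03-fold, between positions 17830188 and 17830879 in an intron of Spaca6. Mir27a, of a cluster active in myeloid cells, was 2.87-fold lower and Mir574 2.24-fold lower. Among the higher hairpins, Mir7033 had 295 and 1915 counts (7.75-fold), and Mirlet7c-1 was 2.22-fold higher, Mir6539 2.07-fold and Mir6236 2.05-fold. Mirlet7c-2, the more abundant copy of let-7c, was at a log2 ratio of 0.32, with 647186 and 677409 counts. The rule for named features also gave Gm24245 (2.59-fold higher), n-TSaga9 (2.12-fold higher), Gm47285 (2.11-fold higher) and Gm47294 (2.74-fold lower), which the annotation types as miRNA. By its symbol n-TSaga9 is a serine tRNA gene, so its counts can be those of a tRNA. Gm47285 shares 57 nt in a row with the 5S rRNA gene n-R5s102 and Gm47294 shares 38 nt with Rn7s1, the 7SL RNA of the signal recognition particle, so their counts can be divided with those RNAs.

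These hairpins lie at separate sites of GRCm38. Mir9-2 lies on chromosome 13 from 83738814 to 83738885, in an exon of the noncoding gene C130071C03Rik, and Mir34a on chromosome 4 from 150068454 to 150068555, outside other genes. Mir132 lies on chromosome 11 from 75173682 to 75173747 in an intron of 1700016P03Rik, Mir21a on chromosome 11 from 86584067 to 86584158 in an exon of Vmp1, and Mir152 on chromosome 11 from 96850393 to 96850465 in an intron of Copz2. Mir126a lies on chromosome 2 from 26591357 to 26591429 in an exon of Egfl7, and Mir187 on chromosome 18 from 24429110 to 24429170, outside other genes. Mir7033 lies on chromosome 5 from 135383730 to 135383810 in an intron of Pom121.

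Among the lists fixed before the data were examined, the inflammation-responsive miRNAs stood lowest in this comparison. Their median log2 ratio over 10 measured hairpins was -0.55, at percentile 0.40 of 10000 random lists of the same size matched on mean expression, and it stayed below 0 under each scaling. The random lists drew single hairpins, while Mir132 and Mir212 come from the same primary transcript. That percentile can therefore overstate how far the list stands apart. Mir9-2, Mir132, Mir212 and Mir21a were at least 2-fold lower and Mir187 at least 2-fold higher. Mir155, the main miRNA of macrophage activation, was at 0.22 and Mir146 at 0.02, and Mir146b at -0.70. The let-7 family, whose tailed precursors Dis3l2 degrades, had a median of 0.11 over 11 hairpins (percentile 80.4), with Mirlet7c-1 higher and Mirlet7e lower. That median falls below 0 when all features set the scale, which moves every ratio of this comparison by -0.16.

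The myeloid and haematopoietic list had a median of 0.17 over 9 hairpins (percentile 84.3). It was -0.04 once counts of host transcripts were added to their hairpins, because miR-223, a marker of the myeloid lineage, is counted mainly on its host transcript F630028O10Rik: that unit had 152898 counts with the label shNS and 28415 with the label shDis3l2 (log2 -2.17). The miR-15-16 family stood at 0.28 (6 hairpins, percentile 93.2), the miR-23-27-24 clusters at -0.36 (5 hairpins, percentile 9.23) and the miR-30 family at 0.06 (6 hairpins, percentile 63.0), the last below 0 with all features as the scale. Among the miR-23-27-24 hairpins, Mir24-2 had 303 counts with the label shNS and 232 with the label shDis3l2. Most miR-24 reads were counted on the host of Mir24-1, 2010111I01Rik (158552 and 96287 with the hairpin). Of the miR-17-92 and paralogous clusters, Mir106b and Mir93 were both at 0.45. Mir29a was at -0.28 and Mir29b-1 at 0.07, and of the Drosha-independent capped miRNAs Mir320 was at 0.35 and Mir484 at -0.14. Mir29b-2, another copy of miR-29b, and Mir29c were counted mainly on their host A330023F24Rik. That unit had 245226 counts with the label shNS and 129973 with the label shDis3l2, against 676 and 595 for Mir29b-1.

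Markers of other cell types were sparse. The epithelial list stood at 0.74 (4 hairpins, percentile 96.1), with Mir141 at 0.93 and Mir200c at 0.70, and none of the 4 reached 2-fold. The endothelial and mesenchymal list stood at 0.80 (3 hairpins, percentile 94.9), where Mir126a was the member past 2-fold, and the erythroid and serum list at 0.28 (3 hairpins, percentile 82.1). The muscle list had 1 measured member (Mir1b, 0.07), the neural list 2 (Mir128-1, 0.09, and Mir138-2, -0.61), and the list of pluripotent cells 0 in each of the 4 comparisons.

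Several structured noncoding RNAs, a group that Dis3l2 is known to degrade, were higher in the cell library labelled shDis3l2 when scaled to all counts. Rnu12, the U12 snRNA of the minor spliceosome (chromosome 15, 83149644 to 83149794), had 1670 and 13773 counts, 8.84-fold higher (8.40 to 9.31). Rnu11, its U11 partner, was 5.11-fold higher (4.47 to 5.88), the Y RNA Rny3 (chromosome 6, 47781624 to 47781725) 4.41-fold (4.33 to 4.49), the U1 gene Rnu1a1 2.73-fold and Rn7sk, which holds the elongation factor P-TEFb, 2.15-fold. These were 5 of the 12 measured members of the list of structured Pol III and RNP RNAs, whose median was 0.58 (percentile 86.1), and 0 were 2-fold lower. Rny1 (log2 -0.18), Rn7s1 (-0.25), Rmrp (-0.27) and Rpph1 (-0.19) were lower but within 2-fold, and the interval of Rpph1 included 0. Rnu5g (0.74), Rnu7 (0.42) and Vaultrc5 (0.27) were higher within 2-fold. Beyond the list, 90 of 247 snoRNAs and scaRNAs were at least 2-fold higher and 1 lower, and 10 of 25 snRNAs higher and 1 lower; these classes were chosen after their values were seen. Their ratios moved with annotated length (Spearman rho 0.424 across 272 RNAs, which are not replicates).

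Of the mRNAs on the fixed lists, few were measured in cells. Of the interferon-stimulated genes, Ifit1, an RNA-binding antiviral effector, had 123 counts with the label shNS and 244 with the label shDis3l2 (log2 1.09), and Rsad2, the antiviral enzyme viperin, 85 and 46 (-0.78). Of the RNA decay and tailing genes, Dis3l2 is given above, Tut7, a uridylyltransferase, was at 0.12 and Xrn1, an exonuclease of mRNA decay, at -0.49, for a list median of 0.12 (percentile 47.1).

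The second comparison asked the same of the vesicles. In the vesicle library labelled shDis3l2, Mir9-2 was 9.79-fold lower than in that labelled shNS (log2 -3.29, 95% interval -3.81 to -2.84), Mir338, an intronic miRNA of Aatk, 2.75-fold lower, Mir125a 2.21-fold lower and Mir21a 2.09-fold lower. Mir365-1 and Gm47294, with 656 and 503 counts in the library labelled shNS, had 0 in that labelled shDis3l2 and were at least 117-fold and 89.4-fold lower, but Mir365-1 summed with its copy had 3240 and 2848 counts and a log2 ratio of 0.72. Among the highest ratios were those of Mir6236 (4.12-fold higher), Mir6240 (3.82-fold) and Mir1981 (3.34-fold), which were not searched for shared stretches. These also included n-TStga1 (7.18-fold, from 32 and 124 counts), n-TSaga9 (3.88-fold) and Gm47304 (3.40-fold), whose whole 70 nt are shared with the 7SL RNA Rn7s1. Like n-TSaga9, n-TStga1 has the symbol of a serine tRNA gene.

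Of 195 hairpins, 34 were at least 2-fold higher and 12 at least 2-fold lower in the vesicle library labelled shDis3l2, but this split depended on the scale. It was 19 and 22 with TMM factors, 20 and 22 with DESeq2 size factors, 7 and 50 with all features as the scale, and 64 and 11 with host transcripts added. The median of all hairpins was 0.22, and -0.13, -0.13 and -0.64 under those first 3 alternatives. Further named hairpins were Mir7068 (4.77-fold higher, and 2.06-fold with its host added), Gm24245 (3.70-fold) and Mir8108 (3.19-fold), and Mir96 (2.44-fold lower), Mir362 (2.17-fold), Mir103-2 (2.11-fold) and Mir1843a (2.10-fold). Mir103-1, the other copy of miR-103, went the other way at a log2 ratio of 0.29, with 7509 and 4888 counts. Mir17, with 0 and 754 counts, was at least 471-fold higher, but most reads of its cluster are counted on the host transcript Mir17hg. That cluster with its host had 157437 and 68956 counts and a log2 ratio of -0.28.

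Mir365-1 lies on chromosome 16 from 13453840 to 13453926 and Mir338 on chromosome 11 from 120014765 to 120014862. Mir6236 lies on chromosome 9 from 110281287 to 110281409 and Mir6240 on chromosome 5 from 114851948 to 114852064, both outside other genes, and Mir1981 on chromosome 1 from 184822407 to 184822488 in an intron of Marc2. Mir96 lies on chromosome 6 from 30169446 to 30169551, and Mir17 on chromosome 14 from 115043671 to 115043754 in an exon of Mir17hg.

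The fixed miRNA lists stood closer to the middle in vesicles than the inflammation-responsive list did in cells. That list had a median of -0.17 over 8 hairpins (percentile 10.9), with Mir9-2 and Mir21a at least 2-fold lower and Mir155 at 0.19. The myeloid and haematopoietic list also stood at -0.17 (9 hairpins, percentile 5.46), with Mir150, of mature lymphocytes, 2.20-fold higher and miR-223 with its host at -0.26. The miR-23-27-24 clusters stood at -0.19 (4 hairpins, percentile 25.4), the miR-15-16 family at -0.04 (6, percentile 21.6) and the miR-30 family at -0.05 (6, percentile 24.7).

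Other list medians of the vesicle comparison lay above 0 on the main scale and changed sign under another. The let-7 family at 0.06 (11 hairpins, percentile 65.6) and the erythroid and serum list at 0.21 (6, percentile 45.6) fell below 0 with TMM factors, which moved each ratio by -0.35. The epithelial list at 0.77 (4, percentile 77.0), the endothelial and mesenchymal list at 0.63 (3, percentile 67.7) and the miR-17-92 list at 0.49 (4, percentile 75.1) fell below 0 with all features as the scale, which moved each ratio by -0.86. Mir29a was at -0.54 and Mir29b-1 at 0.67, Mir320 at 0.66 and Mir484 at -0.62, and Mir128-1, the 1 measured neural hairpin, at 0.37, while no muscle hairpin was measured. Mir29b-1 had 1395 counts with the label shNS and 1180 with the label shDis3l2. Mir29b-2 and Mir29c with their host had 25629 and 12539.

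Interferon-stimulated mRNAs were higher in the vesicle library labelled shDis3l2 on the scale of all counts, though from few reads. All 13 measured genes lay above 0, with a median log2 ratio of 0.69 at percentile 99.6, against a median of 0.32 for all genes tested. Irf7, the transcription factor that drives interferon alpha genes, had 74 and 174 counts (log2 1.27), Cxcl10, a chemokine for T cells, 81 and 165 (1.07) and Oasl1, a repressor of Irf7 translation, 59 and 118 (1.04). These 3 were the members past 2-fold. Irf7 lies on chromosome 7 from 141262706 to 141266481, Cxcl10 on chromosome 5 from 92346638 to 92348889 and Oasl1 on chromosome 5 from 114923240 to 114937915. The RNA decay and tailing list stood at 0.31 over 9 genes (percentile 53.0), with none past 2-fold and Exosc10, a nuclease of the exosome, at 0.83.

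The structured noncoding RNAs stood low in the same comparison. The list median was -0.25 over 12 RNAs (percentile 0.10 of the random lists), where Rnu7, the guide of histone mRNA processing (chromosome 6, 124741225 to 124741286), was 2.92-fold lower with 10869 and 3603 counts. On the scale of miRNA counts this median was 0.61, so its sign depends on the scale. Rny3 was 1.10-fold higher, Rn7s1 1.54-fold higher and Rnu12 1.69-fold lower. The snoRNAs and scaRNAs had 0 of 135 at least 2-fold higher and 23 lower, with a median of -0.60. On the scale of miRNA counts 6 were higher and 1 lower, with a median of 0.26, and on that of counts outside miRNAs 0 and 39.

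**Figure D2:**
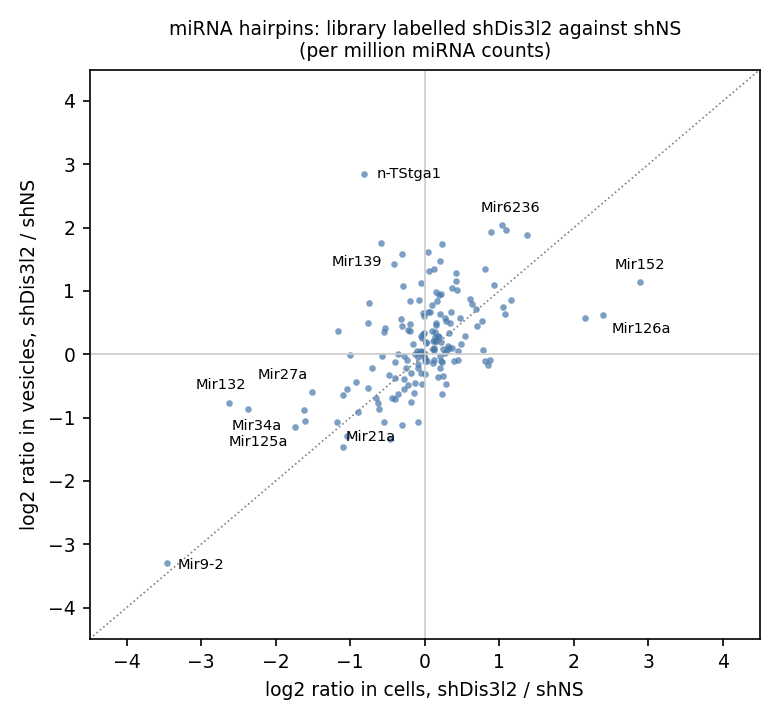
Each point is 1 of 164 miRNA hairpins with a count in all libraries; the axes give the log2 ratio of CPM over miRNA counts between the libraries labelled shDis3l2 and shNS, in cells (horizontal) and in vesicles (vertical), and the dotted line marks equal ratios. Mir9-2 lies near that line at -3.46 and -3.29, while Mir152 (2.88 and 1.15) and Mir126a (2.39 and 0.63) lie below it. Mir126a is drawn without the reads counted on its host Egfl7.

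The design also asks whether the ratio between the labels is the same in vesicles and cells. Across 166 hairpins measured in both, the ratios had a Pearson r of 0.394 and a Spearman rho of 0.511, across miRNAs, which are not independent replicates. Of the hairpins at least 2-fold apart, 4 were higher in both and 7 lower in both, where independent lists of those sizes would share 1.19 and 1.08, and 0 were opposite. The ratios of vesicles and cells share no library.

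Of the 166, 25 differed by at least 2-fold between the vesicle ratio and the cell ratio with a difference beyond its counting error, 19 higher in vesicles and 6 lower. With TMM factors the split was 10 and 15, with DESeq2 size factors 10 and 14. The largest differences upward were those of n-TStga1 (3.65 on the log2 scale), Gm47304 (2.35), Mir3069 (1.89), Mir132 (1.85) and Mir139 (1.84). Mir132 was lower in both compartments, at -2.62 in cells and -0.78 in vesicles. The largest differences downward were those of Mir126a (-1.77), Mir152 (-1.74) and Gm44456 (-1.58), besides Mir365-1 and Gm47294, which were at 0 in 1 vesicle library. In vesicles Mir126a alone had 4920 counts with the label shNS and 4051 with the label shDis3l2. With its host Egfl7 it had 8314 and 9764 there, and 5468 and 23522 in cells, so its difference depends on where reads are counted.

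The remaining comparisons asked which RNAs vesicles carry in another proportion than the cells that release them. On the scale of miRNA counts the erythroid pair Mir144 and Mir451a was far higher in vesicles labelled shNS than in cells, with 5 and 477 counts for Mir144 (337-fold) and 4 and 376 for Mir451a (324-fold, 141 to 1344). Mir150 was 273-fold higher (17 and 1233 counts), Mir3107, the hairpin of miR-486b that is abundant in red cells, 166-fold and the mesenchymal Mir143 166-fold. Mir181b-2 was 5.65-fold lower in vesicles, Mirlet7e 3.57-fold, Mir34a 2.90-fold, Mir125a 2.85-fold and the hypoxia-induced Mir210 2.43-fold. Mir181b-1, another copy of miR-181b, went the other way, with 79.2 CPM in cells and 254 in vesicles. In the libraries labelled shDis3l2, Mir143 was 292-fold higher in vesicles, Mir451a 274-fold (107 to 1559) and Mir150 271-fold. Mir144 was at least 539-fold higher there, and Mir181b-2 was 7.22-fold lower. Mir181b-1 had 146 CPM in those cells and 237 in vesicles, so the lower ratio is that of 1 hairpin copy.

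With the label shNS, 71 of 210 hairpins were at least 2-fold higher in vesicles and 14 lower. With TMM factors the split was 49 and 41, with DESeq2 size factors 44 and 57, and with all features as the scale 29 and 135. With the label shDis3l2 it was 77 and 19 of 206 on the main scale, 50 and 72 with TMM factors, 49 and 83 with DESeq2 size factors, and 33 and 145 with all features. The all-hairpin median was 0.44 and 0.50 in the 2 comparisons, -0.18 and -0.54 with TMM factors, -0.38 and -0.70 with DESeq2 size factors, and -1.40 and -2.04 with all features as the scale. Directions close to 0 are therefore relative to the other miRNAs of the same library.

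With the label shNS, the hairpins with the highest ratios included several that share sequence with other RNAs or were at 0 in cells. Mir8108 had 0 and 3540 counts (at least 4574-fold higher), with a log2 ratio of 6.94 once its copies and host were added (143 and 4547 counts), and Mir8114 0 and 237 (at least 306-fold). Gm47301, which shares 56 nt with 5S rRNA, was 672-fold higher, Gm44456, which shares 82 nt with n-TStga1, 613-fold, and Mir6981 267-fold. Since n-TStga1 has the symbol of a serine tRNA gene, the counts of Gm44456 can be those of a tRNA. Mir92-1 had 1 and 4972 counts, a ratio of 12851 with an interval from 3458 to 761434, but its cluster with the host Mir17hg had 435925 and 157437 counts (log2 0.49). Lower ones besides those above were Snord43, a snoRNA in an intron of Rpl3 that the annotation types as miRNA (6.49-fold), Mir28a (2.98-fold), Mir6539 (2.88-fold), Mir322 (2.63-fold) and Mir350 (2.46-fold).

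With the label shDis3l2, Gm47301, Mir8108 and Mir92-1 were at 0 in cells and at least 22391-fold, 12222-fold and 10305-fold higher in vesicles, where Mir8108 with its copies and host had a log2 ratio of 8.65. Mir17 was at least 1528-fold higher by its own counts, and its cluster with the host was at -0.05. Mir8114 was 293-fold higher (3 and 168 counts, 115 to 1668) and Gm44456 205-fold. Mir365-1 and Gm47294, at 0 in these vesicles, were at least 163-fold and 48.2-fold lower, but Mir365-1 summed with its copy had a log2 ratio of 2.45, in the other direction. Mir7033 was 9.13-fold lower, Snord43 5.23-fold, Mir6539 3.53-fold, Mir350 3.04-fold, Mir338 2.85-fold, Mir210 2.69-fold and Mir152 2.64-fold.

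Mir144 and Mir451a lie side by side on chromosome 11, from 78073005 to 78073070 and from 78073170 to 78073241, Mir150 on chromosome 7 from 45121757 to 45121821 and Mir143 on chromosome 18 from 61649196 to 61649258, all outside other genes. Mir3107 lies on chromosome 8 from 23142573 to 23142662 in an intron of Gm15816. Mir181b-2 lies on chromosome 2 from 38853830 to 38853918, antisense to Nr6a1, and Mir210 on chromosome 7 from 141221384 to 141221493.

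The fixed list of erythroid and serum miRNAs stood apart in both vesicle comparisons. Its median log2 ratio was 4.63 over 6 hairpins with the label shNS (percentile 99.3) and 4.48 with the label shDis3l2 (percentile 98.8, and the same value with Mir144 at its bound), and 4 of the 6 were at least 2-fold higher in each. The liver miRNA Mir122 was at 1.88 and 2.74, while Mir16-1, the abundant member, was at 0.10 and -0.14. The medium in which vesicles were collected held vesicle-depleted bovine serum, and the table does not tell mouse from bovine reads. Among markers of other cell types, the endothelial and mesenchymal list stood at 2.68 (3 hairpins, percentile 85.2) and 0.61 (4, percentile 36.4), and the epithelial list at 1.22 (4, percentile 68.7) and 0.65 (4, percentile 42.4). Of these 4 medians, that of 2.68 stayed above 0 under every scaling. The muscle hairpin Mir1b was at 0.13 and -0.58, and the neural Mir128-1 at -0.17 and 0.10, with Mir138-2 at 1.98 with the label shNS.

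The let-7 family stood at 0.11 with the label shNS (11 hairpins, percentile 56.7) and 0.02 with the label shDis3l2 (percentile 26.0), and the miR-15-16 family at 0.07 (6, percentile 19.2) and -0.30 (6, percentile 4.51). The myeloid and haematopoietic list stood at 0.37 (10, percentile 52.9) and 0.08 (10, percentile 13.4), the miR-30 family at 0.56 (6, percentile 90.3) and 0.57 (6, percentile 84.2). The inflammation-responsive list stood at -0.17 (10, percentile 7.54) and 0.14 (9, percentile 32.6) and the miR-23-27-24 clusters at -0.54 (5, percentile 5.14) and 0.21 (5, percentile 63.3). Each of these medians above 0 was below 0 with TMM and DESeq2 factors. The miR-17-92 list stood at 1.48 (3, percentile 91.9) and 7.05 (4, percentile 99.5), the latter 5.76 with Mir17 and Mir92-1 at their bounds, and at 0.49 and -0.05 with host transcripts added. Mir29a was at -0.54 and -0.80 and Mir29b-1 at 3.00 and 3.59, Mir320 at 0.41 and 0.73, and Mir484 at 1.28 and 0.80. Mir29b-1 rests on 676 counts in cells and 1395 in vesicles labelled shNS. Mir29b-2 and Mir29c with their host had 245226 and 25629 there, and 129973 and 12539 with the label shDis3l2. The ratio of Mir29b-1 alone therefore does not give the direction of miR-29b in vesicles.

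On the scale of all counts, vesicles held more of the vault, 7SL and Y RNAs and less of the snoRNAs. Vaultrc5, a vault RNA (chromosome 18, 36801866 to 36802008), was 18.1-fold higher in vesicles labelled shNS and 13.0-fold in those labelled shDis3l2, Rn7s1 10.3-fold and 18.9-fold, Rny3 13.1-fold and 3.26-fold, and Rny1 5.14-fold and 4.73-fold. The list of structured Pol III and RNP RNAs had medians of 1.87 (12 RNAs, percentile 14.3, 7 higher and 1 lower) and 1.12 (percentile 5.76, 6 higher and 4 lower). Nuclear RNAs did not go 1 way: Rpph1, the RNA of ribonuclease P, was 10.7-fold and 21.2-fold higher in vesicles, Rn7sk 4.17-fold and 2.58-fold higher, and Rnu12 3.58-fold and 53.7-fold lower. Of the snRNAs, 19 of 32 were at least 2-fold higher and 2 lower with the label shNS, and 11 of 31 higher and 9 lower with the label shDis3l2. Of the snoRNAs and scaRNAs, 194 of 206 were at least 2-fold lower in vesicles with the label shNS and 221 of 223 with the label shDis3l2. Among tRNA families by anticodon, 42 of 47 were at least 2-fold higher in vesicles in both comparisons, and Lys-CTT, picked after the values were seen, had 33942 counts in cells and 1625990 in vesicles (52.0-fold) with the label shNS, and 39526 and 1027721 (27.2-fold) with the label shDis3l2.

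mRNA fragments were a larger share of vesicle counts as a whole, and the fixed mRNA lists moved with them. The interferon-stimulated genes had medians of 1.67 (6 genes, percentile 32.1) with the label shNS and 2.60 (13, percentile 87.2) with the label shDis3l2, with Ifit1 lower in vesicles at -2.62 and -3.51. The RNA decay and tailing genes had medians of 1.96 (6, percentile 33.2) and 1.85 (7, percentile 16.8), with Dis3, the exosome nuclease, at 2.75 and 2.81. Dis3l2 itself was at 5.45 with the label shNS and -2.74 with the label shDis3l2.

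**Figure D3:**
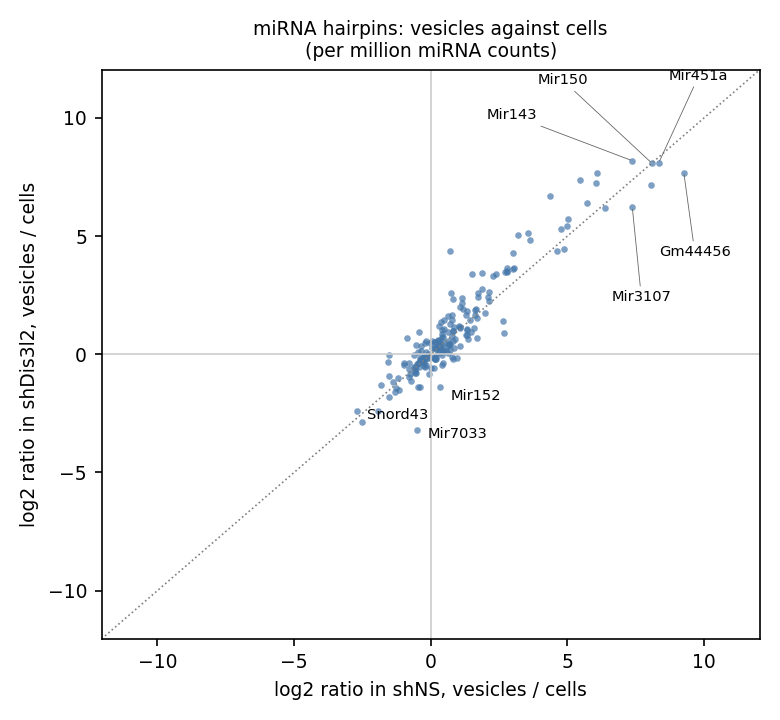
Each point is 1 of 192 miRNA hairpins with a count in all libraries; the axes give the log2 ratio of CPM over miRNA counts between vesicles and cells, with the label shNS (horizontal) and the label shDis3l2 (vertical), and the dotted line marks equal ratios. Mir451a (8.34 and 8.10) and Gm44456 (9.26 and 7.68) lie at the top right, and Mir7033 (-0.48 and -3.19) below the line. Gm44456 shares sequence with n-TStga1, named as a serine tRNA gene.

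The ratio of vesicles to cells was close between the labels. Across 200 hairpins measured in both comparisons, Pearson's r and Spearman's rho were both 0.903, across miRNAs. Of the hairpins at least 2-fold apart, 61 were higher in vesicles with both labels, where independent lists would share 25.2, and 10 were lower with both, where 1.19 would be shared, and 0 were opposite. An additive edgeR fit over the 4 libraries, which takes the interaction of compartment and hairpin as its error, called 117 of 255 hairpins for compartment and 12 for the hairpin label (Benjamini-Hochberg adjusted, with 134 and 45 at an unadjusted p under 0.05). The additive DESeq2 fit called 119 and 22.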

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

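The tests on Dis3l2, on the share of miRNA counts, on hairpins at 0 and on clustered hairpins were chosen only after the result was seen, while that on RNA length was written down beforehand.

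Dis3l2 had 13232 counts in the cell library labelled shDis3l2 against 42 in that labelled shNS. Reads shared with another transcript are argued against only for annotated sequences already abundant in the cell library labelled shNS. Of 112 transcripts outside Dis3l2 that share at least 18 nt with it, the highest held 178 counts (Kidins220) there, against 13189 counts gained. Their counts in the cell library labelled shDis3l2 were not compared, so a transcript that itself rose with that label is not covered. tRNA and SINE sequences were not searched. Reads of the expressed hairpin itself could give counts on a short stretch of the gene; 99.8% of the counts lie on 1 of 6 transcripts, but the table holds no read positions, so this stays open. The vesicle library labelled shNS had 1713 counts, which such reads would not give if its label is right. Since a mistaken label stays open and was not tested, this does not decide either. A protein-coding transcript went with the labels, with 7.74 counts in cells and 13.0 in vesicles labelled shNS and 0 in both labelled shDis3l2. These counts are too few to decide.

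snoRNAs and snRNAs were higher in the cell library labelled shDis3l2, with class medians of 0.58 and 0.74 on the scale of all counts. A lower share of miRNA counts in that library is argued against as the whole reason: scaled to counts outside miRNAs, the median over 272 RNAs was still 0.33, with 69 at least 2-fold higher and 2 lower. Libraries that differ in the length of RNA they captured may explain part of the pattern, since the ratio followed annotated length (Spearman rho 0.424), with medians of 0.24 up to a length of 104.5 nt and 0.94 above it. Of the 136 shorter RNAs, 35 were at least 2-fold higher and 0 lower, but this cannot decide whether length is the whole reason. These values are on the scale of all counts, where the lower miRNA share also raises the ratios, and lengths still vary among the shorter RNAs. Lower Dis3l2 activity also stays open, because the labels divide the libraries in the same way.

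In 14 ratios, over 10 hairpins, 1 library had 0 counts and the other at least 100. Division of reads between a hairpin and its host transcript may account for the 3 ratios of the miR-17-92 cluster, where the largest log2 ratio of the sums was 0.35 in size. Of the other 8 ratios with a copy or host, the sum added at least 100 counts in 5, and 2 of these, both of Mir8108, stayed at least 2-fold in the same direction (6.94 and 8.65). Division stays open for Gm49346, for Mir365-1, whose sums (0.72 and 2.45) lay above 0 where the hairpin alone was lower, and for Gm47294 and Gm47301, where the sums added few counts or 0 and left out 7SL and 5S rRNA. The last 3 ratios (Mir8114, Mir411 and Mir144) have no annotated copy or host.

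The label ratio (shDis3l2 to shNS) of vesicles minus that of cells was -9.76 for Mir365-1, a ratio that rests on the 0 just described. It was 3.65 for n-TStga1, named as a serine tRNA gene, and 2.35 for Gm47304, hairpins that share sequence with Gm44456 and with 7SL RNA. For Mir139 it was 1.84, from -0.41 in cells and 1.43 in vesicles. For Mir664 it was 1.37, from -0.29 and 1.08. For Mir1983, Mir574 and Mir423 it was 1.56, 1.54 and 1.03, and their opposite directions in cells and vesicles were lost on the scale of all counts, where the vesicle ratios were -0.04, -0.49 and -0.02. Beyond counting error none of these differences has a test.

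The class median of snoRNAs and scaRNAs was 1.18 lower in vesicles than in cells (a difference of -1.18) and that of snRNAs differed by -1.09. On the scale of miRNA counts the vesicle medians were 0.26 and 0.52, so the opposite directions were lost. They were kept on the scale of counts outside miRNAs, with 0.29 and 0.45 in cells and -0.75 and -0.49 in vesicles.

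In the vesicle library labelled shDis3l2, Gm42427 had 1419710 counts, Gm43305 had 539081 and the 4.5S RNA 20690.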

How the results depend on the processing

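Host units, the restriction to symbols starting with Mir and, for other genes, the scale of miRNA counts were added after the data were examined; the other alternatives were planned.

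No paired analysis was possible because each group has 1 library, so there are no replicates to match; the additive fits below take the interaction as their error. For the labels in cells, 34 hairpins at least 2-fold apart became 79 with a minimum of 10 counts, and the additive fits called 12 (edgeR) and 22 (DESeq2). For the labels in vesicles, 46 became 110 with at least 10 counts, 20 with at least 1000 and 75 with host units, and the same additive fits apply, with 12 and 22. Vesicles against cells with the label shNS gave 85, and 164 with all features as the scale, 196 with at least 10 counts and 45 with at least 1000. With the label shDis3l2 the 96 became 178, 220 and 49. A lower minimum admits more hairpins by construction; for the other settings the cause was not tested.

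The correlation of the label ratios in cells and vesicles was 0.394, and 0.612 with at least 1000 counts and 0.105 with at least 10. Hairpins whose label ratio differed between vesicles and cells numbered 25, and 46 with host units. The cause was not tested for these.

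Of 39 list medians, 13 changed sign with TMM factors, 13 with DESeq2 factors and 5 with host units. Among medians that stood outside the central range of random lists, the direction of 2 reversed. The miR-17-92 list in vesicles against cells, label shDis3l2, went from 7.05 to -0.0478 with host units, which add the reads counted on Mir17hg. The structured Pol III and RNP list for the labels in vesicles went from -0.25 to 0.61 on the scale of miRNA counts, by construction, since the miRNA share differs between those libraries. Of the other list medians, TMM and DESeq2 factors each moved 30 and left 9, a minimum of 10 counts moved 10 of 50, host units moved 7 and the scale of miRNA counts moved 8. Of 20 named hairpins per comparison, all 20 stayed listed with TMM and with DESeq2 factors, 18 in cells after thinning and 19 in vesicles with a pseudocount of 5. The scale of all features was not part of this check. It moved the label ratios by -0.16 in cells and -0.86 in vesicles. Named higher hairpins such as Mir6236 in cells (1.03) and Mir1981 in vesicles (1.74) fall under 2-fold on it, while lower ones move further down.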

Other observations

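The test of clustered hairpins was chosen only after the result was seen, and the repeat without hairpins at 0 was added after the vesicle result.

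Mitochondrial tRNAs, which serve translation inside mitochondria, were among the RNAs least present in vesicles. Of 22 measured, all 22 were at least 2-fold lower in vesicles on the scale of all counts, with a median ratio 34.4-fold lower with the label shNS and 44.8-fold lower with the label shDis3l2. Mitochondrial rRNAs took 0.978% of the cell library and 0.0152% of the vesicle library labelled shNS, and 0.0170% of the vesicle library labelled shDis3l2. Cytoplasmic tRNAs went the other way: Arg-TCT was 60.3-fold and 41.4-fold higher in vesicles and Gly-TCC 46.8-fold and 43.4-fold, while Gly-GCC was 4.05-fold and 3.29-fold higher and Pro-AGG was the 1 family at least 2-fold lower with the label shNS. In cells 6 of 46 tRNA families were at least 2-fold higher with the label shDis3l2 and 0 lower, among them SeC-TCA, the selenocysteine tRNA, with 796 and 3304 counts (log2 2.15).

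Among snoRNAs in cells, the box C/D genes named Snord had a median of 0.50 between the labels (27 of 75 higher, 0 lower), the box H/ACA genes named Snora 0.67 (12 of 29 higher, 1 lower) and the Cajal-body genes named Scarna 0.66 (3 of 8 higher, 0 lower). Rnu3b1, a U3 gene of rRNA processing, had 13050 and 47879 counts (1.98). Gm24379, typed as a miscellaneous RNA on chromosome 2 from 158487602 to 158487687, shares 24 nt with Rny1. It was 2.79-fold higher with the label shDis3l2 in cells and 2.63-fold lower in vesicles.

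Gm42427, on chromosome 5 from 44137980 to 44143271, had 1020447 counts in the vesicle library labelled shNS and 4841 in the cells, 229-fold higher, and 245-fold with the label shDis3l2. Gm43305, on chromosome 14, was 214-fold and 293-fold higher. The transcripts share 112 nt, and Gm42427 shares 180 nt with Gm4316 and 104 nt with AI506816, so it is not known which of these genes the counts belong to. Without read positions this was not tested; aligning the reads to repeat consensus sequences and to the bovine genome would tell.

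Hairpins of 1 genomic cluster had closer label ratios in cells than shuffled ones, on average. Over 61 hairpins in 25 clusters the mean distance from the cluster mean was 0.14, against a median of 0.43 in shuffled clusters, and 0 of 10000 shufflings were as low, also without the miR-99b cluster. The Mir132 and Mir212 cluster had a mean of -2.75, the miR-99b cluster -1.65, and Mir182, Mir183 and Mir96 -1.06, while Mir181a-1 with Mir181b-1 had 0.87 and Mir141 with Mir200c 0.82. Not every cluster was even: Mir23a and Mir27a were at -0.40 and -1.52. Mir24-2 of that cluster was at -0.13 from 303 and 232 counts. Mir24-1, the other copy of miR-24, had 158552 and 96287 with its host, so the value of Mir24-2 covers few miR-24 reads. These ratios may therefore reflect the primary transcripts, as a hypothesis found and tested on the same libraries. In vesicles the distance was 0.45 and 2083 of 10000 shufflings were as low, and without hairpins at 0 in a library it was 0.30 with 11 as low, so the vesicle result depends on 2 hairpins. Nascent RNA or primary-transcript PCR for Mir132, Mir99b and Mir181a-1 in replicate cultures would test it.

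The length of RNA captured remains a candidate explanation of the snoRNA and snRNA ratios in cells (rho 0.424). Libraries from the same RNA with a fixed size selection, or Northern blots of Rnu12 and Rny3, would tell a longer insert from a higher level. For Dis3l2, read positions on its transcript would show whether the 13232 counts fall on the hairpin target, and a quantitative PCR outside that target would check the label.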
